A study of Mus musculus with 17 samples.

How the data were processed

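Expression was measured on 17 single-colour Illumina mouse bead arrays, 1 per sample, from cortex and hippocampus of C57Bl/6J pups on the day of birth, 8 female and 9 male per the labels. Per the labels' protocols, total RNA was extracted with a lipid tissue kit from untreated animals on standard chow and labelled with biotin. Scanner, scan software and chip were not given in the sources used here. The deposited table of probe intensity holds 1 signal per probe and array on a linear scale, which the values show to be neither background-subtracted nor normalized between arrays, and the deposited detection p-value of each probe beside it. The detection p-values are whole multiples of 1 over 936 within 0.001, as a share of negative-control probes would be. Sex was taken from the labels, and each column was matched to its sample by the sex and number in its name.

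A second table holds the authors' processed intensity values of the same arrays on a linear scale, with no description of their making. Compared with the raw signals, 12 of its columns equal a quantile normalization over all 17 arrays without background subtraction. The other 5 columns, arrays numbered 7 or higher in each sex, were in addition changed probe by probe, so that their mean came within 1% of the mean of the 12 for 99.998% of probes, against 17.2% in the quantile-normalized raw signals. The scale and the lack of centring per gene are thus known for that table, and the reason for the adjustment is not given in the sources used here. This array set is treated below as a possible batch. It holds 6 females and 6 males in one part and 2 females and 3 males in the other.

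The main analysis started from the raw intensities. Background was corrected with neqc in limma 3.58.1 (R 4.3.3, statmod 1.5.0), with the background distribution taken from the detection p-values and an offset of 16, followed by quantile normalization and log2. Probes with a detection p under 0.01 on at least 8 arrays were tested, 16571 of 45281. The platform annotation gave 34885 probes 1 gene symbol, 18 several and 10378 none, and none was named from a probe with several. Symbols were updated, and chromosomes taken, by Entrez identifier from a RefSeq gene table of assembly GRCm38.p6, which was used for names and chromosomes only. The tested probes covered 9452 genes, with 13784 autosomal, 440 X-linked and 3 Y-linked probes and 2344 with no or another chromosome.

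Sex was tested with lmFit and eBayes, without covariates, on all 17 arrays, and p-values were adjusted by the Benjamini-Hochberg method over all tested probes at 0.05, and separately over the autosomal probes. X-linked against autosomal calls were compared by Fisher's exact test. A probe with a detection p of 0.01 or more on every array of a group is described as not well above background there. Its fold is given as a bound, the mean of the brighter group against the mean, over the dim group's arrays, of the higher of the lowest detected signal and the probe's own. Of 30 gene lists fixed before the data were examined, the 29 without the Y-linked list were tested with camera (two-sided, preset inter-gene correlation 0.01, at least 5 tested members, 1 probe per gene, the one with the highest mean), against the other tested genes and without Y-linked genes. Each was repeated with an estimated correlation and with fry. Intervals of list means are 95% intervals over arrays. Array summaries were compared by exact two-sided permutation tests.

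Genes were named by a rule fixed before the data were examined. It took every measured Y-linked, X inactivation centre or escape gene, the probes past the threshold (at most 30), and the genes with the next smallest p until 20 genes outside those lists were named. It also took, from each other list, up to 4 members past the threshold over the list alone or otherwise the 2 with the smallest p, and the most abundant member of each list of another cell type or tissue. Ide, Idh3a, Gbx2 and the genes of the array sets and of the second regional list were named after their values were seen. A gene is represented by its brightest tested probe.

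The numbers of the samples are shared between the sexes. Same-numbered samples deviated from their group means together, with correlations of 0.13 to 0.57 over the tested probes for all 8 pairs. The array sets account for part of this, since the correlations were -0.12 to 0.18 after set means were removed. The fit with the numbers as a replicate block (male 9 left out) is therefore given beside results it changes.

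The fits were tested on simulated data with the real probes' means, array set differences and residual SDs, 200 changed probes in each of 5 rounds of 16571 probes. Without a block 5.97%, 64.5% and 98.8% of probes changed by 1.19, 1.41 and 2-fold were recovered, with 2 false calls per round, and with the array set as a block 17.0%, 83.3% and 99.7%, with 8 false calls per round. Shifting the radial glia list by 0.2 (log2) in 20 rounds with independent genes and the array set as a block, camera called it in 20, and called 3 of 560 other lists. Members of the real lists can move together between arrays, so these rates do not carry over to the real lists.

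Alternatives fixed before the data were examined were no background correction, normexp with an offset of 50, scaling to the 75th percentile, no normalization, the authors' processed values, array weights, trended and robust variances, a replicate block, leaving out each array, other filters and thresholds, a fold threshold of 1.2, the Wilcoxon test, 1 probe per gene, and other forms of the list test. Added after the data were seen were the array set as a block, each set alone, the list test with an estimated correlation in each set and leaving out each array, and the block together with other settings. The chip as a block was not run, since the files used here do not name the chip. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.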

Results

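Gene expression was measured in cortex and hippocampus dissected together from untreated C57Bl/6J mouse pups on the afternoon of birth, between 1 and 3 pm on postnatal day 0. The design asks which transcripts differ between the sexes at birth in this tissue. Each of 17 samples, 8 from females and 9 from males, was measured on 1 Illumina bead array carrying 45281 probes. The hybridized material was prepared from total RNA and labelled with biotin. Per array, 16018 to 17433 probes were detected above the negative controls. The median raw signal was 84.2 ± 4.31 in females (SD, n = 8) and 86.4 ± 6.34 in males (SD, n = 9), with an exact two-sided permutation p of 0.420. Values below are log2 signals after background correction and quantile normalization, differences are male minus female, and errors beside means are SD over 8 female or 9 male arrays. Adjusted p-values are from limma over the 16571 probes tested, and the number of arrays limits the precision. The labels number the samples within each sex but do not state that each came from a separate pup, so the p-values measure the spread between these samples.

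The sexes were separated by Xist, Eif2s3y, Kdm5d and Eif2s3x, and by 1 probe with no gene name in the table used here. Xist, the noncoding RNA that coats the inactive X chromosome, had a log2 signal of 9.37 ± 0.52 in females and 4.25 ± 0.08 in males, where it was not well above background on any array. It was at least 23.9-fold higher in females (adjusted p = 4.1e-16). Eif2s3y, the Y-linked gene for the gamma subunit of translation initiation factor eIF2, was not well above background on any female array (4.24 ± 0.05) and reached 8.72 ± 0.15 in males, a difference of at least 15.3-fold (adjusted p = 1.7e-21). Kdm5d, a Y-linked histone H3 lysine demethylase, was at least 2.49-fold higher in males (6.10 ± 0.30 against 4.22 ± 0.03, not well above background in females, adjusted p = 4.4e-11). Eif2s3x, the X-linked counterpart of Eif2s3y, was 1.39-fold higher in females, at 9.55 ± 0.15 against 9.07 ± 0.08 (log2 difference -0.48, SE 0.08, adjusted p = 0.0044), and all 8 female arrays lay above every male array.

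In all, 8 probes passed an adjusted p of 0.05, 3 higher in males and 5 higher in females. Of these, 5 were X-linked (4 probes for Xist and 1 for Eif2s3x), 2 were Y-linked, and none of the 13784 autosomal probes passed. The remaining Xist probes were at least 21.8-fold, 4.28-fold and 3.69-fold higher in females. The unnamed probe, ILMN_2899599, was detected on every array and was higher in males, at 8.96 ± 0.13 against 7.53 ± 0.35 (log2 difference 1.42, SE 0.12, adjusted p = 1.1e-07), with all 9 male arrays above every female array. X-linked probes were over-represented among the calls against autosomal probes, 5 of 440 against 0 of 13784 (Fisher's exact test, two-sided, p = 2.8e-08). With 1 probe per gene the counts were 2 of 301 X-linked genes against 0 of 9125 autosomal genes (Fisher's exact test, two-sided, p = 0.0010). Both tests count Xist, whose difference follows from sex itself, and the first counts it with 4 probes that are not independent. Eif2s3x was the only other X-linked gene called, so the tests do not show an excess across X-linked genes.

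The 17 arrays fell into 2 sets that the labels do not name, 12 numbered 1 to 6 in each sex (6 female, 6 male) and 5 numbered 7 or higher (2 female, 3 male). Both sexes were in each set. The first principal component of the tested probes held 34.7% of the variance and separated the sets (-11.7 ± 2.61 against 28.0 ± 4.23, SD, exact permutation p = 0.00016, the smallest these permutations can give) but not the sexes (exact permutation p = 0.952). Between the sets 6262 probes passed an adjusted p of 0.05, 2961 higher and 3301 lower in the 5 arrays. With the set as a block in the fit, a setting chosen after the data were seen, 11 probes passed, including the 8 named above. The 3 added probes were all higher in females, and measured the X-linked genes Kdm6a (2 probes) and Erdr1 (1 probe). Leaving out each of the 17 arrays in turn, the brighter Kdm6a probe missed the threshold in 8 cases (adjusted p up to 0.104), the dimmer one in 0 and the Erdr1 probe in 11 (up to 0.163). Within the 12 arrays 7 probes passed, and within the 5 arrays 7 passed. In both, Eif2s3x was the call lost, with log2 differences of -0.43 (adjusted p = 0.126) and -0.62 (adjusted p = 0.9996).

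**Figure D1:**
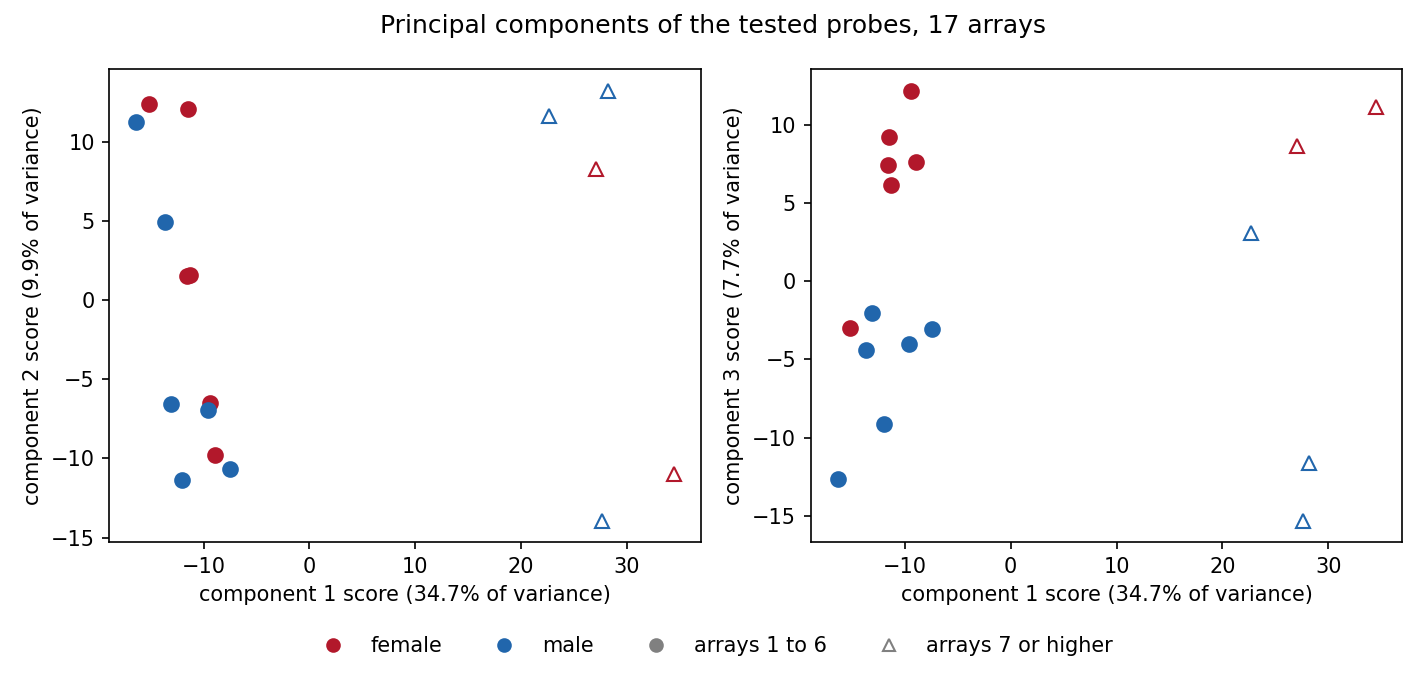
Scores of the 17 arrays on principal components 1 and 2 (left) and 1 and 3 (right) of the tested probes, in arbitrary log2-based units, each point 1 array, coloured by sex and shaped by array set. The 5 arrays numbered 7 or higher lie apart from the 12 others on component 1, which held 34.7% of the variance, and the means of the sexes differ on component 3 (7.68% of the variance), with overlap of single arrays.

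All 3 tested Y-linked genes had higher means in males, and 2 passed over all probes tested. Uty, the Y-linked homologue of the demethylase gene Kdm6a, was dim, detected on 4 of 8 female and 7 of 9 male arrays, at 4.62 ± 0.33 and 4.89 ± 0.27 (log2 difference 0.27, SE 0.13, adjusted p = 0.9996). Adjusted over the list alone, 3 of 3 passed, Uty with a p of 0.04995. The other Uty probes were detected on no array of either sex. Females lack a Y chromosome, so the signal of the tested Uty probe on 4 female arrays cannot come from Uty. Its difference is therefore not secure evidence for this gene. Usp9y, Zfy1, Zfy2 and Sry, the testis-determining gene, had probes on the array that were detected on too few arrays to be tested. A second probe for Eif2s3y was likewise too dim for the test.

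The list of X inactivation centre RNAs and genes reported to escape X inactivation, a process that silences 1 X chromosome in female cells, had 8 tested members. Of these, Xist and Eif2s3x were lower in males over all probes and 6 did not pass; adjusted over the list alone, 4 passed, with Kdm6a and Pbdc1 added. Kdm6a, a histone H3 lysine 27 demethylase, measured 7.91 ± 0.34 in females and 7.52 ± 0.34 in males (log2 difference -0.39, SE 0.15, adjusted p = 0.9996). With the array set as a block the difference was -0.44 (SE 0.08, adjusted p = 0.024), and its second probe gave -0.51 (adjusted p = 0.0096). Within the 12 and the 5 arrays the first probe gave -0.45 and -0.43, neither past the threshold (adjusted p = 0.237 and 0.9996). Pbdc1 measured 7.80 ± 0.09 and 7.58 ± 0.17 (log2 difference -0.22, SE 0.08, adjusted p = 0.9996), with 0.031 over the list alone. Ddx3x, an RNA helicase gene, gave -0.23 (SE 0.15), Bgn, for the matrix proteoglycan biglycan, gave 0.05 (SE 0.12), and the deubiquitinase gene Usp9x gave 0.09 (SE 0.13). Med14, a Mediator subunit gene, gave 0.14 with its brighter probe and -0.23 with a second, and neither passed (adjusted p = 0.9996). Kdm5c, Mid1, Utp14a, Car5b and Shroom4, also on the list, had probes on the array that were detected on too few arrays to be tested.

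As a set the escape list was lower in males, with a median log2 difference of -0.23 and a camera adjusted p of 1.0e-10, and adjusted p = 8.9e-05 with an estimated correlation. Without Xist its 7 members had a median of -0.22 and a mean of -0.15, 4 of them higher in females (camera p = 0.00018; p = 0.0015 with an estimated correlation). The list of X-linked genes with a Y copy, which shares Eif2s3x, Kdm6a, Ddx3x and Usp9x with it, had a median of -0.13 over 6 members (camera adjusted p = 0.0024; adjusted p = 0.022 with an estimated correlation). Over this list alone 2 members passed, Eif2s3x and Kdm6a. Both lists also passed with the array set as a block (camera adjusted p = 1.4e-09 and 0.00051). Without the block, Eif2s3x was the only member of either list, apart from Xist, that was called over all probes. How much of either shift remains without Eif2s3x was not tested.

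**Figure D2:**
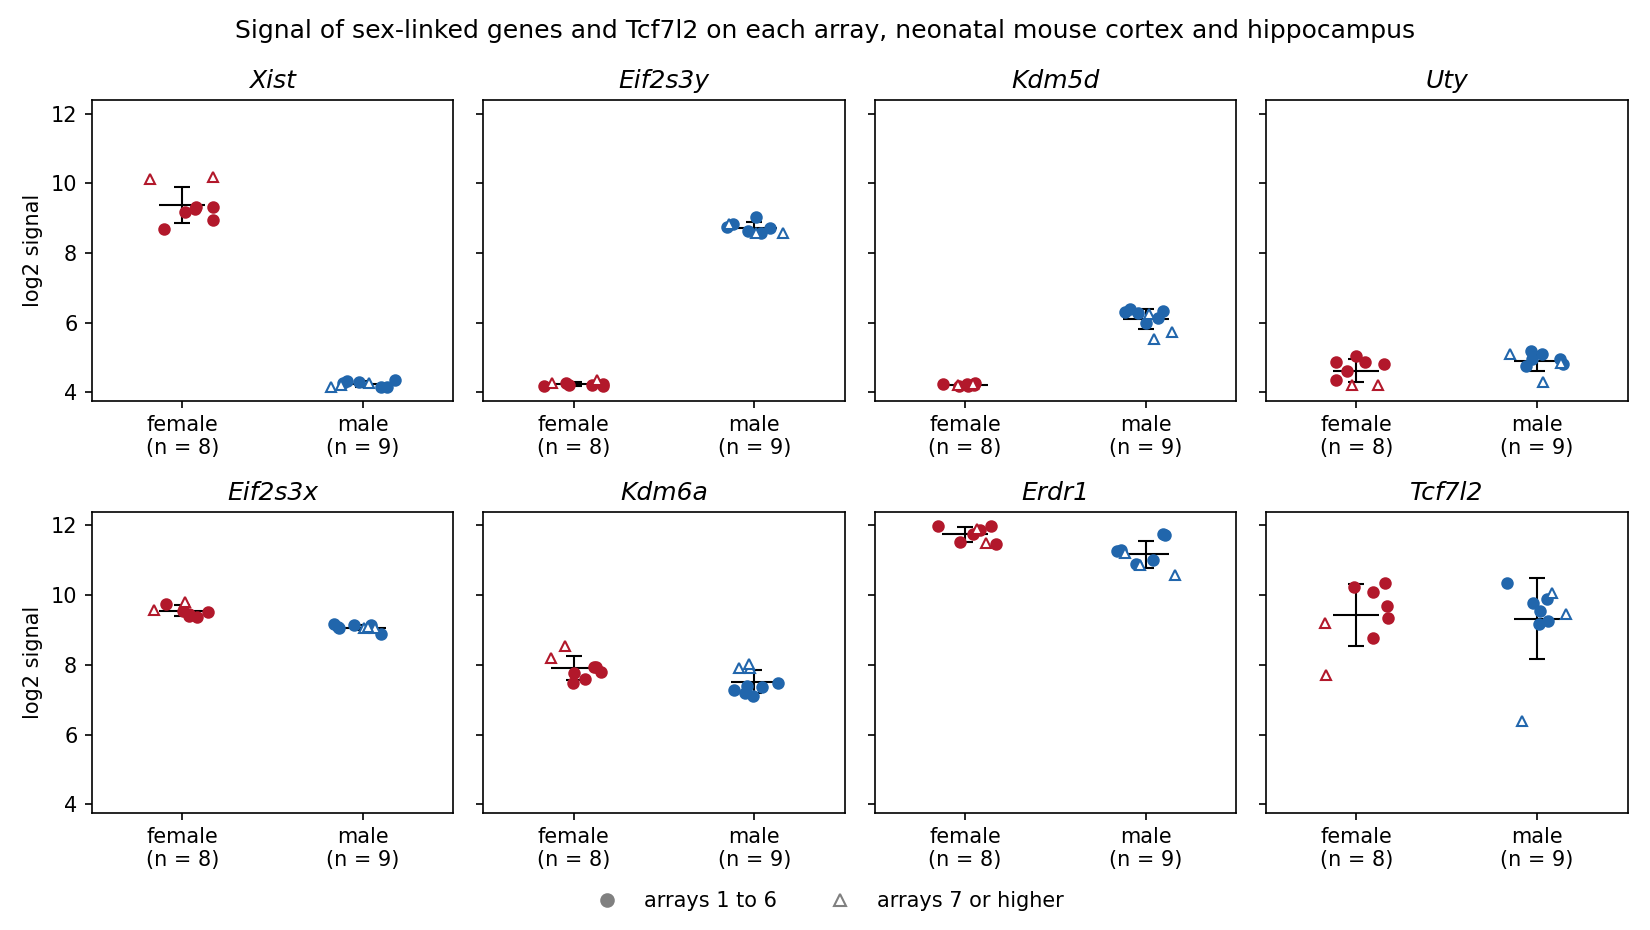
Log2 signal of 8 genes on each array, females in red (n = 8) and males in blue (n = 9), filled circles for arrays 1 to 6 and open triangles for arrays 7 or higher, with the mean as a horizontal bar and SD as error bars. Xist, Eif2s3y, Kdm5d and Eif2s3x do not overlap between the sexes, Kdm6a is higher in the 5 later-numbered arrays of both sexes, and Tcf7l2 spans 6.38 to 10.35 with no difference between the sexes past the threshold.

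Erdr1, an X-linked gene in the table used here that lies by the pseudoautosomal region shared by both sex chromosomes, came next by p-value. Its brighter probe measured 11.75 ± 0.21 in females and 11.18 ± 0.39 in males (log2 difference -0.57, SE 0.14, adjusted p = 0.889), and 5 of 8 female arrays lay above every male array. Its dimmer probe gave -0.62 (adjusted p = 0.9996), and with the array set as a block -0.56 (adjusted p = 0.033). The brighter probe did not pass with that block (adjusted p = 0.279). The sample numbers of the labels, used as a replicate block on numbers 1 to 8, gave 13 probes past the threshold, 3 higher in males and 10 in females. The 5 added were both tested probes of Kdm6a, both of Erdr1 and 1 for the autosomal gene Ide, an insulin-degrading protease (log2 difference -0.54, adjusted p = 0.026).

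Without a block or with the array set as a block, no autosomal gene passed an adjusted p of 0.05, either among all probes or with the adjustment over the 13784 autosomal probes alone. Ide, with the replicate block, did not pass over the autosomal probes alone. At an unadjusted p under 0.05 there were 422 autosomal probes (3.06%), and 805 (5.84%) with the array set as a block. Among the genes with the smallest p-values outside the sex-linked lists, Trpm3, a cation channel gene of choroid plexus and sensory neurons, measured 5.44 ± 0.24 in females and 5.87 ± 0.23 in males (log2 difference 0.43, SE 0.11, adjusted p = 0.915). Its other tested probes gave 0.20 and -0.13. Pip5k1b, for a phosphatidylinositol phosphate kinase, gave 0.36 (SE 0.09, adjusted p = 0.889) and was detected on 1 female and 8 male arrays. With the array set as a block and a single array left out, it passed over all probes without female 4 (adjusted p = 0.022), as did 1 probe for Idh3a (adjusted p = 0.023; without a block and with all arrays it gave 0.32 and the other Idh3a probe 0.02), and 2700081O15Rik passed without female 2 (adjusted p = 0.043), none of them over the autosomal probes alone. Stag2, an X-linked cohesin subunit gene, gave 0.30 (SE 0.08), with a second, dimmer probe at 0.04. Klk8, for the serine protease neuropsin, gave 0.35 (SE 0.10), and Cpt2, for a mitochondrial carnitine palmitoyltransferase, gave 0.27 (SE 0.08). Positive values were also measured for 2700081O15Rik (0.41), Mea1 (0.32), Nkx2-3 (0.30), Rarres2 (0.29), Abhd14b (0.29) and Fam185a (0.26). The other tested Rarres2 probes gave 0.02 and -0.09. Values higher in females were measured for 1700093K21Rik (-0.43), 1110017D15Rik (-0.41), Rtbdn (-0.30), Rrp15 (-0.29), Scrg1 (-0.29), Dhx8 (-0.28), Zswim8 (-0.28) and the histone gene H2ac19 (-0.25). For each of these the adjusted p was 0.9996, except for Trpm3 and Pip5k1b as given.

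The precision of the arrays bounds these differences. The median SE of an autosomal probe was 0.11 on the log2 scale, and for 98.8% of the autosomal probes the 95% interval of the difference lay within 1.5-fold in either direction. The highest absolute difference was 0.56. In simulated data with the arrays' own spread, 64.5% of probes changed by 1.41-fold and 98.8% of probes changed by 2-fold were recovered, but 5.97% of those changed by 1.19-fold. Each simulated round held 200 changed probes, while 8 probes were called in the real data. The adjusted threshold is stricter where fewer probes change, so these rates overstate the recovery of a few changed probes. These intervals and simulated folds refer to the processed signal. The offset of 16 used in background correction shrinks the differences of dim probes, so for those the folds do not bound the change in RNA.

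Genes of sex steroid signalling, steroid synthesis, DNA methylation and histone deacetylation did not pass. Of the steroid receptors and coregulators, 6 were bright enough to be tested, 3 with higher means in males, with a mean difference of 0.03 (95% interval -0.14 to 0.20, camera adjusted p = 0.926). The steroid receptor chaperone gene Fkbp4 gave 0.06 (SE 0.10) and the orphan receptor gene Esrrb 0.14 (SE 0.21). Of 10 genes of steroid synthesis and metabolism, 4 had higher means in males (mean 0.03, interval -0.04 to 0.10). Hsd17b7, for a hydroxysteroid dehydrogenase, gave 0.24 (SE 0.13) and Srd5a3, of the steroid reductase family, 0.21 (SE 0.12). Of 17 genes of DNA methylation and histone deacetylation, 8 had higher means in males (mean 0.00, interval -0.05 to 0.06). The histone deacetylase gene Hdac9 gave 0.22 (SE 0.08), and the de novo DNA methyltransferase gene Dnmt3b gave -0.17 (SE 0.08).

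Neuronal and progenitor genes did not pass the test between the sexes. Of 19 genes of excitatory projection neurons, 14 had higher means in males (mean 0.04, interval -0.15 to 0.23), with Bcl11b, a transcription factor gene of deep-layer neurons, at 0.15 (SE 0.10) and the kinase gene Camk2b at -0.12 (SE 0.08). GABAergic interneuron genes, 9 of 15 with higher means in males, had a mean of 0.01 (interval -0.07 to 0.09), with Nxph1, for a neurexin ligand, at 0.18 (SE 0.08) and the somatostatin gene Sst at -0.16 (SE 0.12). Radial glia and intermediate progenitor genes had the lowest p of the lists that did not pass. Of these, 11 of 15 had higher means in males, with a mean of 0.08 (interval -0.01 to 0.18, camera adjusted p = 0.151; adjusted p = 0.772 with an estimated correlation). With the array set as a block the mean was 0.07, and its interval, 0.00125 to 0.136, excluded 0. That interval is not adjusted for the number of lists, and the list did not pass with the block (camera adjusted p = 0.322, and 0.989 with an estimated correlation). Without female 6 or male 4 the list passed with the preset correlation (adjusted p = 0.048 and 0.028), but not with an estimated one (adjusted p = 0.329 and 0.279). The Notch target gene Hes1 gave 0.24 (SE 0.09), and Eomes, a marker of intermediate progenitors, gave 0.30 (SE 0.16). Of 23 cell cycle genes, 10 had higher means in males (mean -0.01, interval -0.11 to 0.10), with the centromeric histone gene Cenpa at -0.16 (SE 0.08) and the replicative helicase gene Mcm5 at -0.17 (SE 0.09).

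Markers of glia, vessels, blood and neighbouring tissue, measured as possible differences in dissection, did not pass either. Astrocyte genes had a mean of -0.05 (interval -0.13 to 0.04), with the connexin gene Gja1 at 0.16 (SE 0.09), Aldh1l1 at -0.15 (SE 0.13) and the abundant glutamate transporter gene Slc1a3 at 11.17 ± 0.20 and 11.10 ± 0.10. Oligodendrocyte lineage genes had a mean of 0.00 (interval -0.09 to 0.09), with Olig1 at 10.44 ± 0.13 and 10.48 ± 0.24, Gpr17 at a difference of 0.17 (SE 0.10) and Cspg4 at -0.18 (SE 0.08). Microglial genes had a mean of 0.04 (interval -0.04 to 0.11), with the fractalkine receptor gene Cx3cr1 at 0.24 (SE 0.10), Aif1 at 0.18 (SE 0.12) and Laptm5 at -0.08 (SE 0.11). Endothelial and pericyte genes had a mean of -0.01 (interval -0.09 to 0.08), with the tight junction gene Cldn5 at 0.02 (SE 0.08) and the angiopoietin receptor gene Tek at 0.22 (SE 0.11). Genes of meninges and fibroblasts had a mean of 0.04 (interval -0.09 to 0.16), with the growth factor gene Igf2 at 0.02 (SE 0.09), Slc22a6 at 0.23 (SE 0.13) and Lum at 0.22 (SE 0.13).

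The choroid plexus list had a mean of 0.02 (interval -0.14 to 0.18), and its transthyretin gene Ttr measured 13.49 ± 0.12 in females and 13.49 ± 0.23 in males, with Sostdc1 at a difference of 0.16 (SE 0.12) and Kcne2 at 0.11 (SE 0.15). Red blood cell genes had a mean of -0.04 (interval -0.16 to 0.08), with the globin genes Hbb-bs at -0.07 (SE 0.09) and Hba-a1 at -0.11 (SE 0.10). The striatal list had a mean of -0.05 (interval -0.24 to 0.14), with Meis2 at 0.12 (SE 0.11) and the prodynorphin gene Pdyn at -0.26 (SE 0.21). The hippocampal list had a mean of -0.05 (interval -0.16 to 0.06), with the semaphorin co-receptor gene Nrp2 at -0.36 (SE 0.16) and Ociad2 at 0.17 (SE 0.11). The thalamus, hypothalamus and midbrain list had the widest interval, -0.44 to 0.33 around a mean of -0.06, with Nkx2-1 at -0.29 (SE 0.14) and Prkcd at -0.08 (SE 0.11). Its most abundant member Tcf7l2, a transcription factor gene of the thalamus, measured 9.42 ± 0.88 in females and 9.32 ± 1.16 in males. The list's median was -0.15 within the 12 arrays (camera adjusted p = 0.044; adjusted p = 0.772 with an estimated correlation) and 0.37 within the 5 arrays (camera adjusted p = 0.017; adjusted p = 0.748 with an estimated correlation), so neither direction held when the correlation of its members was allowed for.

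**Figure D3:**
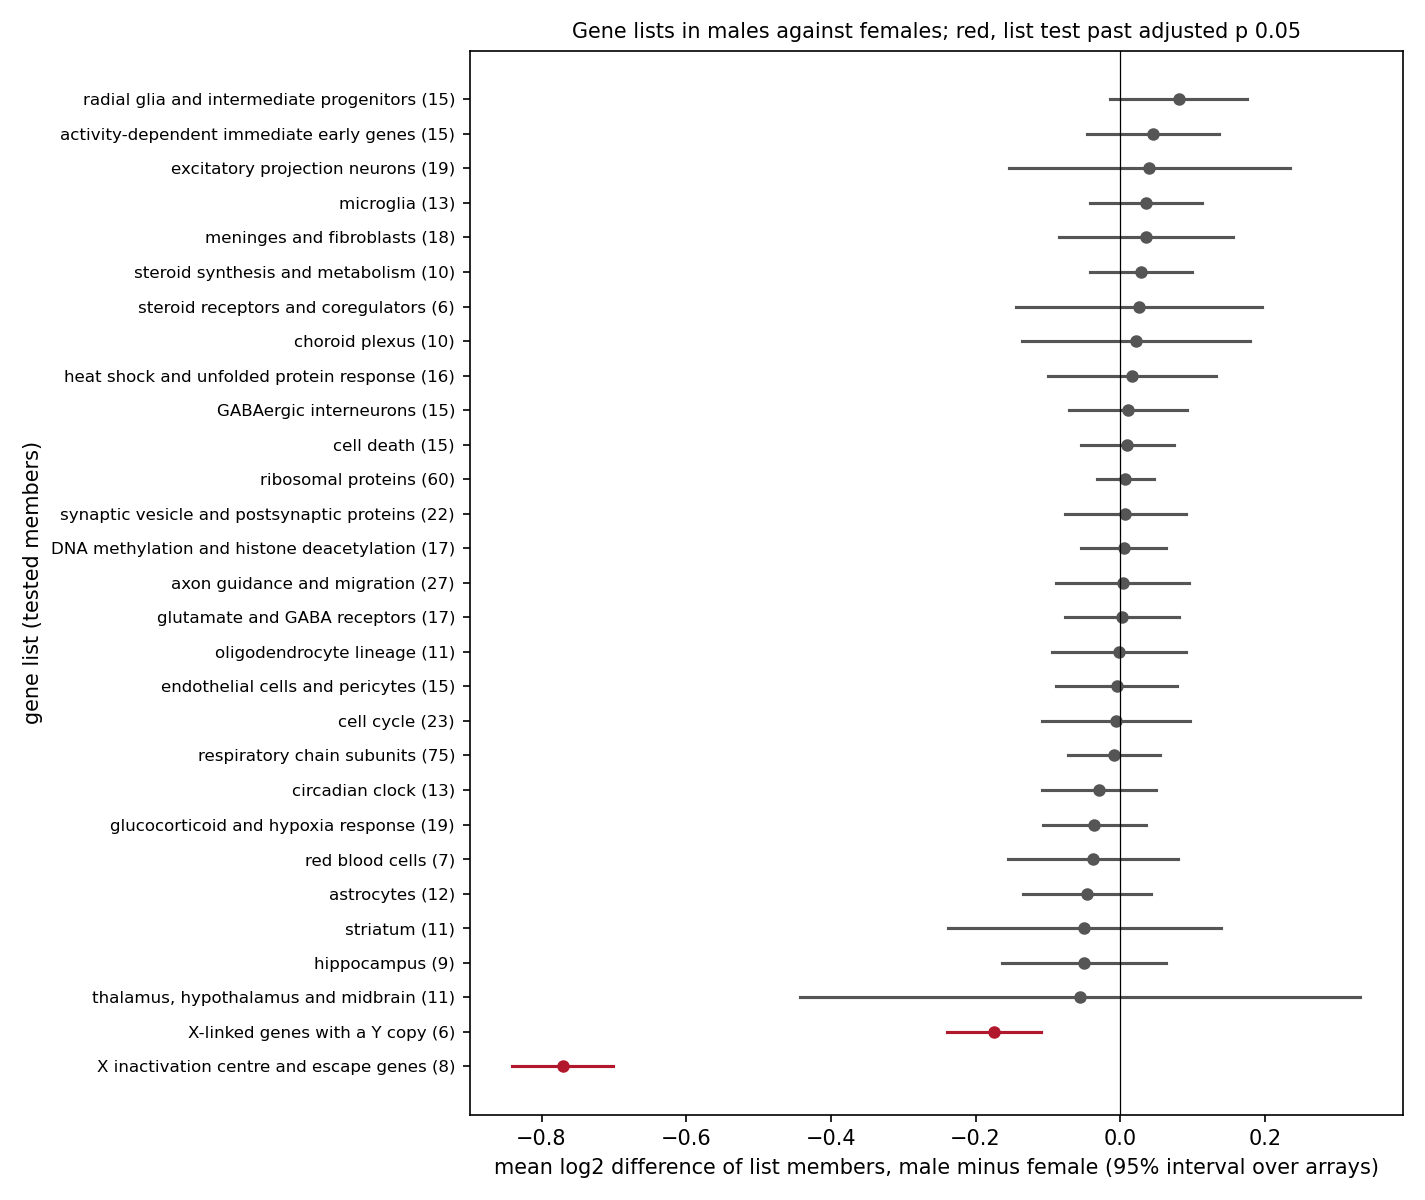
Mean log2 difference of each gene list's tested members, male minus female, with its 95% interval over the 17 arrays, lists sorted by mean and labelled with the number of tested members. In this fit without a block the 2 X-linked lists (red) lie below 0, and the intervals of the 27 other lists lie between -0.44 and 0.33 and include 0.

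Of the lists of cell function, immediate early genes had a mean of 0.04 (interval -0.05 to 0.14), with the phosphatase gene Dusp6 at 0.20 (SE 0.08) and Ier3 at 0.18 (SE 0.09). Glucocorticoid and hypoxia response genes had a mean of -0.04 (interval -0.11 to 0.04), with the metallothionein gene Mt1 at -0.21 (SE 0.10) and the sulfotransferase gene Sult1a1 at -0.29 (SE 0.14). Circadian clock genes had a mean of -0.03 (interval -0.11 to 0.05), with Cry2 at -0.18 (SE 0.09) and Per2 at -0.18 (SE 0.11). Cell death genes had a mean of 0.01 (interval -0.05 to 0.07), with the BH3-only gene Bbc3 at 0.18 (SE 0.15) and the cytochrome c gene Cycs at 0.09 (SE 0.07). Glutamate and GABA receptor genes had a mean of 0.00 (interval -0.08 to 0.08), with Grm8 at 0.13 (SE 0.09) and Gabrg3 at -0.17 (SE 0.12). Genes of synaptic vesicles and the postsynapse had a mean of 0.01 (interval -0.08 to 0.09), with the neuroligin gene Nlgn1 at 0.15 (SE 0.09) and the scaffold gene Shank3 at 0.20 (SE 0.15). Axon guidance and migration genes had a mean of 0.00 (interval -0.09 to 0.10), with Efnb3, for an ephrin, at -0.18 (SE 0.14). Heat shock and unfolded protein response genes had a mean of 0.02 (interval -0.10 to 0.13), with the transcription factor gene Xbp1 at 0.28 (SE 0.10) and the chaperonin gene Hspe1 at -0.19 (SE 0.10). The ribosomal list, taken by symbol prefix and therefore including kinases such as Rps6ka5 (0.14, SE 0.11), had a mean of 0.01 (interval -0.03 to 0.05), with Rps9 at -0.09 (SE 0.06). Respiratory chain subunit genes had a mean of -0.01 (interval -0.07 to 0.05), with Ndufa6 at 0.17 (SE 0.07) and Ndufab1 at 0.15 (SE 0.07).

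Of the 29 lists tested, 2 passed and 27 did not, and among the 501 tested memberships of those 27 lists none passed, either over all probes or adjusted over the list alone. The lowest camera adjusted p among the 27 was 0.151, and 0.322 with the array set as a block. For the lists of steroid synthesis, DNA methylation, endothelial, cell death, glutamate and GABA receptor and synaptic genes, the mean and the median were near 0 and differed in sign. The number of detected probes per array was 16632 ± 464 in females (SD, n = 8) and 16576 ± 316 in males (SD, n = 9), with an exact permutation p of 0.773. The third principal component, 7.68% of the variance, differed between the sexes (7.41 ± 4.65 in females, -6.58 ± 5.94 in males, exact permutation p = 0.00033, 0.0020 adjusted over 6 array summaries), and the 8 called probes held 20.3% of its squared loadings.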

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

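The tests of the thalamic spread given here were chosen after the spread had been noticed, with their bounds written before their results were seen. In 192 groups of 8 or 9 arrays, 15 held a sample far from the others by Dixon's criterion, where chance gives about 1 in 20. Values are log2 signals.

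Tcf7l2, a transcription factor gene of the developing thalamus, was at 6.38 in male 7, with the next male array at 9.17, and female 7, of the same array set, was at 7.70. The tested members of the thalamus, hypothalamus and midbrain list moved together between arrays after sex and array set means were removed, with r of each to the rest of the list between 0.71 and 0.92 across the 17 arrays for Gata3, Lhx9, Gal, Tcf7l2, Irx3, Gbx2, Lhx1 and Rora, but near or below 0.09 for Prkcd, Trh and Nkx2-1. The SD of the list's mean over arrays was 0.34, against a median of 0.06 in 1000 random lists matched on signal. A second list of genes of these regions, written before its test and sharing no gene with the first, followed the score: 16 of 17 genes correlated positively, and the median r of 0.68 lay at percentile 100 of 10000 random lists, whose 95th percentile was 0.20. The overall signal of the array did not account for the spread, with a Spearman rho of -0.12 between the score and the median raw signal. By the bounds written beforehand, the second list (percentile 100) is what varying amounts of diencephalic or midbrain tissue in the dissected samples would give. Explanations other than this and the overall signal of the array were not tested. Averaged over the array sets, the score did not differ between the sexes (difference -0.02, exact permutation p = 0.917 within array sets). The list's median difference ran in opposite directions in the sets, so this average does not show that a difference was absent within each.

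By array set, female 7 and males 7, 8 and 9 belong to the 5 arrays numbered 7 or higher, in which Bgn, Pdyn, Laptm5, Esrrb, Uty, Ttr, Ociad2 and Tcf7l2 were lower than in the 12 others (adjusted p = 0.0034 to 0.030), while the groups compared here were by sex alone. Female 7 had Bgn at 7.37 (next 7.99), the prodynorphin gene Pdyn at 5.63 (next 6.80), the metallothionein gene Mt1 at 10.66 (next 11.07) and the lysosomal gene Laptm5 at 7.28 (next 7.80). Female 2 had Rarres2 at 5.50 (next 5.98) and Eomes, a marker of intermediate progenitors, at 4.45 (next 5.38). Female 3 had Rrp15 at 6.80 (next 7.04), and female 8 had the astrocyte gene Aldh1l1 at 5.58 (next 6.35). Among males, the Y-linked Uty was at 4.30 in male 8 (next 4.76), the transthyretin gene Ttr at 12.996 in male 8 (next 13.38) and the nuclear receptor gene Esrrb at 4.89 in male 7 (next 5.82). Eif2s3x was at 8.88 in male 4 (next 9.04), Ociad2 at 6.59 in male 9 (next 6.84), and 1 Xist probe, not well above background in males, was at 4.40 in male 1 (next 4.29).

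Among the 28710 probes left out of the test for low signal, a second Eif2s3y probe was detected on 5 of 9 male arrays and on 0 of 8 female arrays. In all, 47 such probes were detected on at least 4 arrays of one sex and on none of the other, against a median of 50 (26 to 143) in 200 random groupings, so that the number is no larger than random groupings give.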

How the results depend on the processing

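Settings with the array set as a block or with each set alone, and leaving out arrays with an estimated correlation, were chosen after seeing the data. Without a block, the count of 8 probes (3 higher in males, 5 in females, 5 X-linked) stayed within 1.5 times of itself under the background, scaling, weighting, variance, filter and threshold alternatives, with 7 to 8 probes, except as follows. The authors' processed values gave 12 probes, with 9 higher in females and 8 X-linked. Among the calls gained were the Kdm6a and Erdr1 probes that the array set as a block also added. In these values the probe means of the 5 arrays had already been brought to those of the 12. The fit did not account for that adjustment, so its p-values can be too small. The replicate block gave 13, with 10 higher in females and 9 X-linked, and changed no other call among the named genes than those of Kdm6a, Erdr1 and the autosomal Ide. With 1 probe per gene there were 4, with 2 higher in females, by construction. The Wilcoxon test gave 0 in all, 0 higher in males and 0 higher in females, by construction: the smallest p it can give with 8 and 9 arrays, 8.2e-05, was reached by 9 probes, the 8 among them, for an adjusted p of 0.152, and 28 would have been needed to pass. The array set as a block gave 11, with 8 higher in females and 8 X-linked, and the same 8 and 8 with no background correction (11 probes) or with array weights (11 probes); with 75th percentile scaling it gave 10. Leaving out each array in turn without a block gave 8 to 8 probes, 3 to 3 higher in males, 5 to 5 higher in females, 5 to 5 X-linked and 2 to 3 gene lists, the third being the radial glia list without female 6 or male 4 (adjusted p = 0.329 and 0.279 with an estimated correlation). With that correlation 1 to 2 lists passed, X-linked genes with a Y copy missing without female 7 (adjusted p = 0.072). With the block, leaving out each array gave 9 to 13 probes, 3 to 5 higher in males, 6 to 8 higher in females and 6 to 8 X-linked, and adjusted p of 0.0098 to 0.043 for the dimmer Kdm6a probe, 0.0068 to 0.104 for the brighter one and 0.0096 to 0.163 for the dimmer Erdr1 probe, so that these last 2 calls depend on single arrays. The 13 probes without female 4 included 2 autosomal ones, Pip5k1b and Idh3a, and the 11 without female 2 included 1, 2700081O15Rik, none past the threshold over the autosomal probes alone. Autosomal calls adjusted over the autosomal probes alone were 0 under each alternative run, with 390 to 983 autosomal probes at an unadjusted p under 0.05 in the tests of all, or all paired, arrays at the main filter without a fold threshold or a choice of 1 probe per gene. Eif2s3x was lost with no normalization (adjusted p = 0.853), with a fold threshold of 1.2, and within either array set, where fewer arrays were tested. Of the gene lists, 2 passed under each other alternative, but 0 with X- and Y-linked genes left out, by construction, and 3 within each array set with the preset correlation. Within the 12 arrays the thalamus, hypothalamus and midbrain list was added (median -0.15, adjusted p = 0.044). Within the 5 arrays, 2 females and 3 males, this list turned from a median of -0.05 to 0.37 (adjusted p = 0.017), cell cycle genes were added (adjusted p = 0.011), and X-linked genes with a Y copy did not pass (adjusted p = 0.093). With an estimated correlation these additions were gone: 1 list passed within the 12 arrays, the escape list, and 0 within the 5, with adjusted p of 0.772 and 0.748 for the thalamic list and 0.547 for cell cycle genes in the 5. Among 2914 single-gene values, 2905 kept their call and direction or were uncalled in both, 51 of them with another sign, and none that was called changed sign; among 2144 list values 2134 did, 296 with another direction of the test. The chip as a block was not run, since the files used here do not name it, and robust variances have no counterpart in the list test. Signal over background limits Uty and the second Eif2s3y probe, and the folds of Xist, Eif2s3y and Kdm5d are bounds. In the other cases the cause of a change was not tested.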

Other observations

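Of the tests in this part, the splits for the probes past the threshold (8, 11 and 0), for the lists with the array set as a block and for both X-linked lists, with and without Xist, and the test of principal components were chosen only after the result was seen. The relations between list scores were also chosen after the thalamic spread was seen. The other tests had their bounds written before their results, those of the array sets after the sets, and genes such as Ccnd2 and Neurod2, had been seen.

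Some genes of the thalamus and its neighbours spanned wide ranges between arrays. Tcf7l2 spanned 15.7-fold over the 17 arrays (6.38 to 10.35), with the lowest value in male 7 alone and the next, 7.70, in female 7. Gbx2, a homeobox gene of the developing thalamus, spanned at least 11.9-fold, being not well above background on 2 arrays. Gal, for the neuropeptide galanin, spanned at least 3.74-fold (1 such array) and Rora, a nuclear receptor gene, 2.68-fold. Prkcd, detected on every array, spanned less (1.78-fold), and Nkx2-1, detected on 8 of the 17 arrays, was too dim for a range. In the second list, Zfhx3 (r = 0.96), Zic4 (0.93), Zic1 (0.93), Irx2 (0.86), Gata2 (0.85) and Shox2 (0.83) followed the thalamic score most closely across arrays, and Ramp3 ran against it (-0.54). Scores of other marker lists with sex and array set means removed were set against the thalamic score, 12 relations over 17 arrays. The excitatory projection neuron score was lower where the thalamic score was higher (r = -0.86, permutation p = 2e-05, adjusted 0.00024; rho = -0.82, permutation p = 0.00013, adjusted 0.0016), with r = -0.79 without the 2 arrays farthest from the median and -0.77 within the 12 arrays numbered 1 to 6. The hippocampal score was higher (r = 0.77, permutation p = 0.00037, adjusted 0.0022; rho = 0.79, permutation p = 0.0003, adjusted 0.0018), with 0.87 without those 2 arrays and 0.81 within the 12. The other 10 relations did not pass after adjustment. By r the nearest was that of GABAergic interneurons (r = 0.58, permutation p = 0.015, adjusted 0.061, and rho = 0.56, adjusted 0.066), with r = 0.16 within the 12. By the permutation p of rho it was that of the choroid plexus (rho = 0.57, permutation p = 0.018, adjusted 0.066, and r = 0.46, adjusted 0.198), with r = 0.59 within the 12. The spread of striatal genes (SD 0.19, lowest in female 7, highest in male 9), choroid plexus genes (SD 0.16), genes of meninges and fibroblasts (SD 0.11) and cell cycle genes (SD 0.08) was also above that of all 1000 random lists.

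Between the 5 arrays numbered 7 or higher and the 12 others, 37.8% of the tested probes differed, with the array set fitted beside sex, and the counts of single genes below are to be read against that share. Of 19 excitatory projection neuron genes 10 were higher in the 5 arrays and 1 was lower. Neurod2, a neuronal differentiation factor gene, was higher by 1.05 (log2, SE 0.08, adjusted p = 3.1e-09) and Cux1, a gene of upper-layer neurons, by 0.90 (SE 0.07, adjusted p = 5.7e-09). Of 27 axon guidance and migration genes 13 were higher and 4 lower, of 15 GABAergic interneuron genes 6 were higher and 5 lower, of 17 glutamate and GABA receptor genes 4 were higher and 6 lower, and of 75 respiratory chain genes 7 were higher and 23 lower. No list passed with an estimated correlation. The selenoprotein gene Selenow (1.43, SE 0.09) and the cyclin gene Ccnd2 (1.35, SE 0.10) were among the genes with the smallest p. In the thalamic list 6 of 11 genes were lower and 1 higher, with Gbx2 at -1.43 (SE 0.42, adjusted p = 0.010), a value that includes the 2 arrays where it was dim.

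The difference between the array sets did not follow signal level, with a rho of 0.0067 between mean signal and the difference across probes. For labelling or hybridization that acts probe by probe, the rho of the difference across 3369 pairs of probes for the same gene was 0.24, between the bounds set for and against it, and of 570 pairs with both probes past the threshold 69.5% had the same sign, so this stays open. For another mix of cell types or tissue, 0 marker lists passed with an estimated correlation, the outcome set beforehand as speaking against it; but the excitatory list passed with the preset correlation (adjusted p = 0.00083; adjusted p = 0.433 with an estimated correlation), and a p that misses the threshold with 5 arrays in a set does not exclude a shift, so it also stays open. Litter, collection day and chip are not named in the labels and were not tested.

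Genes on the X chromosome outside the 2 X-linked lists could carry a small excess in females if dosage compensation were incomplete. The per-array median of 291 such genes minus that of 9125 autosomal genes, each centred over arrays, was -0.02 ± 0.04 in females and 0.01 ± 0.03 in males (SD, n = 8 and 9). The difference, female minus male with the array set fitted, was -0.02 (95% interval -0.05 to 0.01), with an exact permutation p of 0.113 within array sets. The interval excludes an excess of 0.1 on the log2 scale, the bound set beforehand.

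Other splits of the arrays bear on the counts. In 100 splits of the 17 arrays into 8 and 9, the real one included, 1 gave at least 8 probes past the threshold, the real one, and the highest other gave 4. Of the 8 probes, 4 measured Xist and 2 measured Y-linked genes, which the sex chromosomes separate in the real split alone. The outcome for the count of 8 was thus largely fixed in advance. In 100 splits within array sets, 2 gave at least 11, and the highest other split gave 46, several times the real count. This was 1 of 99 other splits, the next giving 2, and what it follows was not settled: its sides differed in the thalamic score by -0.42 (exact permutation p = 0.010 within array sets, computed after the split was seen), and of its 46 probes 0 measured members of that list and 1 a gene of the second list, Irx2 (-0.76, adjusted p = 0.043). For autosomal probes the real count was 0, which all 100 splits reach by construction, so these splits test nothing there; the highest other gave 4, and 31 within array sets with the set as a block. At an unadjusted p under 0.05 with the array set as a block, 26 of 100 splits gave at least the 805 autosomal probes of the real one, the highest other 1959, so chance cannot be excluded there. At least 2 gene lists passed in 35 of 100 splits, with 6 as the highest other, and in 36 of 100 splits within array sets with the set as a block, again with 6 as the highest other, so the number of lists passing says little. The p of the escape list was reached by 1 of 100 splits, the real one (3.6e-12, smallest other 0.00018). Since the list holds Xist, this outcome too was largely fixed in advance. The p of the same list without Xist was also reached by 1 (0.00018, smallest other 0.0049). That of the X-linked genes with a Y copy was also reached by 1 (0.00016, smallest other 0.013). None of the 99 other splits reached these values, and 100 splits resolve nothing below 1 in 100. The splits ignored the array sets, and the tests were chosen after the lists had passed. The lists also share genes, so these results are not independent. Whether a sex difference is spread over many autosomal probes could not be settled: of the first 5 principal components of autosomal probes with set means removed, component 5 (6.69% of the variance) had the smallest exact permutation p between the sexes, 0.033, and 0.163 adjusted over the 5. Its scores were carried by female 8 (18.0) and male 9 (-14.2), with the others between -3.23 and 2.65, and without these 2 arrays the exact permutation p was 0.149.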
